A study of Arabidopsis thaliana with 20 samples.

How the data were processed

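RNA was sequenced from whole roots of grafted Arabidopsis thaliana seedlings. The shoot and the root of each graft came from Col-0 wild type (WT) or from cpd, a mutant in the brassinosteroid synthesis gene CPD, in all 4 combinations. Groups are named shoot first: WT/WT, WT/cpd, cpd/WT and cpd/cpd. The series' design text gives 4 graft combinations, but the sample titles of cpd/cpd lack the word Grafted that those of the other groups carry. If cpd/cpd differed in grafting, that could not be told apart from genotype in the comparisons that use it. Each group had 5 replicates and each replicate pooled 3 roots, per the labels. The labels do not say whether the replicates came from separate plates, days or grafting sessions, so p-values measure the spread between these pools of roots.

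Per the labels' protocols, RNA was extracted with the RNeasy Plant Mini Kit and libraries were made with the NEBNext Ultra II Directional kit. STAR and the TAIR10 build are named in the submitters' processing notes, without versions. The counting tool, the annotation release and the strand setting of the counting are not given in the sources used here. The authors deposited 1 table of raw counts per gene, with no normalization, for 32833 gene codes and 20 libraries. Each column was assigned to its sample through the label that carries the same column name, and 0 columns were left unmatched. Overlapping genes and near-identical copies cannot be separated from these counts, and genes in such families are named as uncertain.

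Library totals ran from 13417029 to 32337043 counts. No pair of libraries within a group agreed within sampling noise: over 40 pairs the chi-square per degree of freedom lay between 6 and 51.85. All 20 libraries were used.

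Gene symbols were taken from the reference gene table of assembly TAIR10.1, used for names and for which genes neighbour each other; 32548 of the 32833 codes were in it. Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered by edgeR's default rule by group, which left 20862 genes, and libraries were scaled by TMM. One mean per group was fitted over all 20 libraries, with 16 residual degrees of freedom, by edgeR's robust quasi-likelihood method. Every adjusted p of a gene below comes from its quasi-likelihood F test with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05, and calls of at least 1 on the log2 scale were counted separately. The standard error of a log2 fold change was taken from its F statistic. Levels are CPM, the counts per 1 M counts of the scaled library.

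There were 6 comparisons: root genotype under a WT shoot, root genotype under a cpd shoot, shoot genotype on a WT root, shoot genotype on a cpd root, whole cpd graft against whole WT graft, and the interaction. The comparisons, the tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule took the 6 largest rises and the 6 largest falls among called genes with a mean log2 CPM of at least 3 whose groups did not overlap. For the interaction the overlap condition did not apply, and for the whole grafts the rule took 3 each way. It also took up to 4 members of each list with the smallest adjusted p, and in every comparison CPD, DWF4, BR6OX1, BR6OX2, ROT3, DET2, BAS1 and BRI1. The text names a part of these genes, and 1 gene that the rule took is not reported here. Genes named outside the rule are marked as chosen after their values were seen.

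Gene lists were 38 sets of pathway genes and cell type markers with 569 entries. Of these, 3 entries were left out because the reference gave their code another symbol, and 521 distinct genes were tested. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. Counts of list members are given over all genes and adjusted over the list alone.

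The procedure was tested on simulated counts with the real means and library sizes. In the simulation of the root genotype under a WT shoot, over 20777 genes, it recovered 56.1% of genes changed 1.5-fold, 80.3% of those changed 2-fold and 95.4% of those changed 4-fold, with 6 false calls. For the interaction, over 20766 genes, it recovered 25.4%, 57.6% and 84.8%, with 4 false calls. A raised list of 16 genes was called and 0 of the other lists were. The simulated genes varied independently and the lists held random genes. The simulation therefore does not test false list calls where the members of a list vary together. Nor does it test false gene calls where many genes shift together in a library.

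Alternatives tried were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter and a stricter filter on low counts (CPM of at least 1 in at least 5 libraries), the replicate number as a block, a fit of the compared groups only, a fit without robust estimation, organelle genes left out, a test against a 1.2-fold change, and each library left out in turn. Alternatives chosen after seeing the data were a fit without the library of each group that correlated least with its own group, limma with sample quality weights, and each library left out of the correlations between comparisons.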

Results

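Transcript levels were measured by RNA sequencing in whole roots of 20 pools of grafted Arabidopsis, 5 in each of 4 combinations of shoot and root. Total counts ran from 15892095 to 23942561 in WT/WT, from 13417029 to 29662209 in WT/cpd, from 22040458 to 28857374 in cpd/WT and from 22979686 to 32337043 in cpd/cpd. The first principal component held 24.2% of the variance of log2 CPM and the second 15.7%. In each group 1 library correlated least with its own group: WT/WT replicate 4 (mean r across genes 0.9736), WT/cpd replicate 2 (0.9648), cpd/WT replicate 2 (0.9788) and cpd/cpd replicate 4 (0.974).

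**Figure D1:**
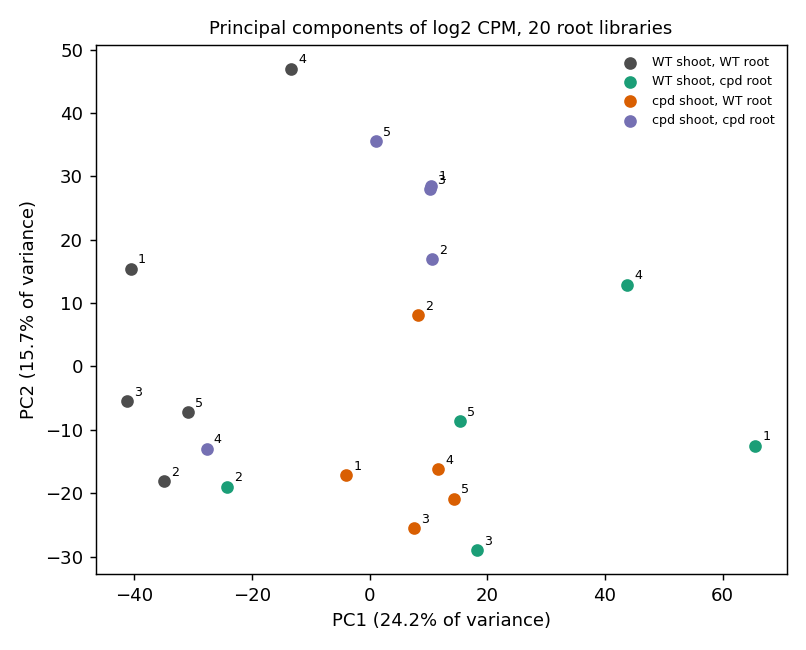
Position of the 20 libraries on the first and second principal component of log2 CPM, coloured by group and numbered by replicate. WT/cpd replicate 2 (-24.3 on PC1) and cpd/cpd replicate 4 (-27.7 on PC1) lie to the left of the other libraries of their groups.

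The mutated gene followed the root genotype in every library. CPD (AT5G05690), a cytochrome P450 of brassinosteroid synthesis, had 45.5 ± 4.93 CPM in WT/WT and 40.9 ± 4.54 in cpd/WT, against 4 ± 0.751 in WT/cpd and 2.84 ± 0.63 in cpd/cpd (SD, n = 5 each). Its lowest value in a WT root was 34.1 CPM and its highest in a cpd root 4.47 CPM. The shoot genotype left no called difference in CPD, with a log2 fold change of -0.15 ± 0.13 (SE) on a WT root (adjusted p = 0.48) and -0.49 ± 0.15 on a cpd root (adjusted p = 0.069). On a cpd root CPD was called in 5 of 21 alternatives (adjusted p from 0.015 to 0.44 over all 21): with DESeq2, without WT/cpd replicate 4, without cpd/cpd replicate 4, without the 4 least typical libraries and with limma sample weights.

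**Figure D2:**
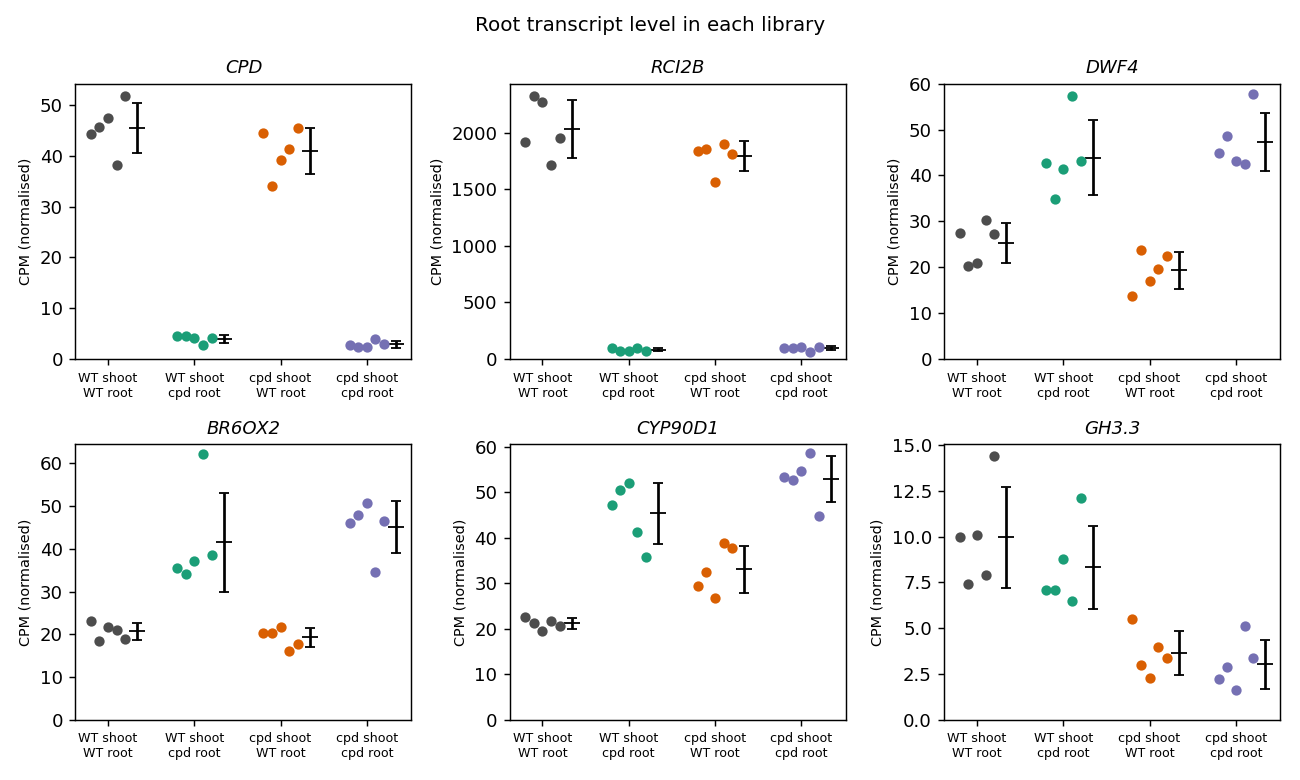
Level of 6 transcripts in CPM in each library, as points by group, with the mean and SD of 5 libraries at the right of each group. CPD and RCI2B are low in every library with a cpd root, DWF4, BR6OX2 and CYP90D1 are higher there on average, and GH3.3 is lower on average under a cpd shoot.

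The first question was what a brassinosteroid-deficient root does under a normal shoot. Other enzymes of brassinosteroid synthesis rose in cpd roots under a WT shoot, and 2 of 5 tested inactivation genes fell, also adjusted over the list alone, with no camera call for that list (adjusted p = 0.15). BR6OX2 (AT3G30180) rose from 20.7 ± 1.95 to 41.5 ± 11.6 CPM (2.01-fold, adjusted p = 0.00053) and CYP90D1 (AT3G13730) from 21.2 ± 1.22 to 45.4 ± 6.77 CPM (2.14-fold, adjusted p = 1.3e-05). DWF4 (AT3G50660) rose 1.74-fold (adjusted p = 0.0039) and ROT3 (AT4G36380) 1.32-fold (adjusted p = 0.0039). BAS1 (AT2G26710) and SOB7 (AT1G17060), which inactivate brassinosteroids, fell by 0.52 and 0.59 on the log2 scale (adjusted p = 0.032 and 0.00099), and BAS1 lost its call in 7 of 21 alternatives, with an adjusted p of up to 0.21. BR6OX1, DET2 and the receptor gene BRI1 had log2 fold changes of 0.17 ± 0.20, -0.07 ± 0.10 and 0.20 ± 0.10 and were not called. As a list, brassinosteroid synthesis had 4 of 10 members higher and 1 lower, CPD itself, both over all genes and adjusted over the list alone, and camera made no call (adjusted p = 0.95).

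Genes of the root's barrier tissue were lower in cpd roots under a WT shoot. Of 10 tested genes of the Casparian strip and endodermis 6 fell, and 7 adjusted over the list alone. CASP4 (AT5G06200) fell from 14.1 ± 2.63 to 5.11 ± 0.617 CPM (adjusted p = 4.8e-05), and CASP1 (AT2G36100) fell by 1 on the log2 scale. Among 16 suberin genes 6 fell, also adjusted over the list alone, with the regulators MYB93 (AT1G34670, -0.75) and MYB92 (AT5G10280, -0.49) and the oxidase CYP86A1 (AT5G58860, -0.58). Camera called the Casparian list (adjusted p = 1.5e-09, and adjusted p = 0.30 with an estimated correlation) and the suberin list (2.9e-05, and adjusted p = 0.37 with an estimated correlation). The Casparian list was also called lower in WT roots under a cpd shoot (camera adjusted p = 0.0039, and adjusted p = 0.54 with an estimated correlation). There 1 of 10 members fell, 2 adjusted over the list alone. CASP4 had 8.35 ± 1.14 CPM in cpd/WT and 6.96 ± 1.59 in cpd/cpd. Iron deficiency genes fell for 4 of 18 members, 10 adjusted over the list alone, among them the regulator BHLH101 (AT5G04150, -1.24 ± 0.24) and the transporter OPT3 (AT4G16370, -0.71 ± 0.18), with a camera adjusted p of 1e-06 and an adjusted p = 0.30 with an estimated correlation.

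Several groups rose. Starch metabolism had 12 of 26 members higher, 16 adjusted over the list alone, such as the glucan kinase GWD1 (AT1G10760, 0.47 ± 0.08) and the ADP-glucose pyrophosphorylase subunit ADG1 (AT5G48300, 0.52 ± 0.11). Phosphate starvation genes rose for 8 of 14 members, 10 adjusted over the list alone, with the transporter PHT1-4 (AT2G38940, 1.53 ± 0.23) and the phosphatases PAP17 (AT3G17790, 1.39 ± 0.28) and PPSPASE1 (AT1G73010, 2.42 ± 0.48). In WT/cpd replicate 1 PPSPASE1 stood at 89.4 CPM against at most 30.2 in the other libraries of that group, and its log2 value was 1.67 without that library. Salicylate and camalexin defence rose for 5 of 9 members, also adjusted over the list alone: PBS3 (AT5G13320, 4.25 ± 0.80), PAD4 (AT3G52430, 1.11 ± 0.17) and ICS1 (AT1G74710, 0.88 ± 0.17) belong to salicylate synthesis and signalling. PBS3 ran from 0.3 to 24.8 CPM in WT/cpd and from 0 to 1.63 in WT/WT, so the groups overlapped. It lost its call with limma sample weights (adjusted p = 0.087). Root hair genes rose for 5 of 19 members, 6 adjusted over the list alone, with PRP1 (AT1G54970) up 3.78-fold and XTH26 (AT4G28850) up 5.17-fold (log2 2.37, and 3.14 without WT/WT replicate 3). These lists were called by camera (adjusted p = 1.5e-09, 2.5e-07, 2.9e-05 and 4.1e-05), and none was with an estimated correlation (adjusted p = 0.30, 0.30, 0.30 and 0.43). BRAVO (AT5G17800), a regulator of stem cell divisions in the root tip, rose 1.99-fold (adjusted p = 0.00024). The list of photosynthesis genes, the marker of shoot tissue, rose for 7 of 27 members, 15 adjusted over the list alone (camera adjusted p = 1.5e-08, and adjusted p = 0.43 with an estimated correlation), and took 0.292% of counts in WT/cpd against 0.197% in WT/WT.

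Over all tested genes, 1972 of 20862 were called, 1291 higher and 681 lower in cpd roots, of which 571 and 77 changed by at least 1 on the log2 scale. Among called genes with a mean log2 CPM of at least 3 and no overlap between the groups, the largest rises were those of CYP71A12 (AT2G30750, 8.63-fold), OCT1 (AT1G73220, 8.4-fold), the near-identical root myrosinase genes BGLU34 (AT1G47600, 5.62-fold) and BGLU35 (AT1G51470, 5.28-fold), whose reads cannot be told apart with certainty, AT1G49570 (3.89-fold) and AT3G19430 (3.84-fold). Single libraries moved these values: on the log2 scale OCT1 rose by 3.07, and by 2.11 without WT/cpd replicate 1, which held 105 CPM against at most 23.4 in the other libraries of that group. Without WT/WT replicate 4 the log2 values of BGLU34 and BGLU35 went from 2.49 and 2.4 to 3.14 and 3. Within the same limit, the largest fall was that of RCI2B (AT3G05890), which encodes a small membrane protein, from 2030 ± 255 to 83.2 ± 15.2 CPM (adjusted p = 1.4e-13). After CPD came AT2G39530 (-1.69), AT5G46900 (-1.60), the chaperone gene ATERDJ3A (AT3G08970, -1.56) and the abscisic acid receptor gene PYL6 (AT2G40330, -1.49). The count was 1112 without WT/WT replicate 1, 1037 without WT/cpd replicate 1, 991 when only these groups were fitted and 3575 without the 4 least typical libraries.

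Under a cpd shoot, the same exchange of root genotype again raised brassinosteroid synthesis genes. DWF4 rose from 19.3 ± 4.04 CPM in cpd/WT to 47.3 ± 6.3 in cpd/cpd (2.45-fold, adjusted p = 0.00011), BR6OX2 rose 2.35-fold (adjusted p = 1e-04) and CYP90D1 1.6-fold (adjusted p = 0.0038). ROT3 (0.03 ± 0.08), BR6OX1 (0.71 ± 0.20), DET2 (-0.08 ± 0.10), BRI1 (0.21 ± 0.10) and BAS1 (-0.41 ± 0.15) were not called. SOB7 fell by 0.44 on the log2 scale (adjusted p = 0.018). Brassinosteroid inactivation was the 1 list that camera called both with the preset correlation (adjusted p = 3e-04) and with an estimated one (adjusted p = 0.038 with an estimated correlation): 1 of its 5 members fell over all genes and 5 adjusted over the list alone. The synthesis list had 3 of 10 members higher and 1 lower, and 6 and 1 adjusted over the list alone, with no camera call (adjusted p = 0.46).

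Suberin and monolignol synthesis genes were lower in cpd/cpd than in cpd/WT roots. Suberin had 3 of 16 members lower, 14 adjusted over the list alone, with the transporter ABCG2 (AT2G37360, -0.47 ± 0.09), the regulator MYB41 (AT4G28110, -1.08 ± 0.25) and the acyltransferase GPAT5 (AT3G11430, -0.54 ± 0.13). Monolignol synthesis had 3 of 14 lower, 7 adjusted over the list alone, including PAL2 (AT3G53260, -0.69 ± 0.13) and C4H (AT2G30490, -0.30 ± 0.07). Camera called both (adjusted p = 6.6e-11 and 0.00025), and neither with an estimated correlation (adjusted p = 0.17 and 0.48). The monolignol list was higher in cpd/WT than in WT/WT (3 of 14 members, 6 adjusted over the list alone, camera adjusted p = 1.9e-05, and adjusted p = 0.32 with an estimated correlation), and PAL2 had 578 ± 60 CPM in cpd/WT against 341 ± 25.9 in WT/WT, 351 ± 57.1 in WT/cpd and 359 ± 78.5 in cpd/cpd. Camera did not call the Casparian strip list under this shoot (adjusted p = 0.15). MYB41 and GPAT5 each lost their call in 9 of 21 alternatives, with adjusted p values of up to 0.17 and 0.32. Starch metabolism had 2 of 26 members higher, 9 adjusted over the list alone, ISA3 (AT4G09020, 0.35 ± 0.08) and the starch synthase gene SS3 (AT1G11720, 0.54 ± 0.12), with camera adjusted p = 0.00031 and adjusted p = 0.48 with an estimated correlation. Root meristem identity had 2 of 11 members higher, 3 adjusted over the list alone, BRAVO (1.72-fold) and PLT3 (AT5G10510, 1.49-fold), with camera adjusted p = 0.0027 and adjusted p = 0.37 with an estimated correlation.

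Camera also called flavonoid, jasmonate, glucosinolate, salicylate and clock genes as lower in cpd roots under a cpd shoot (adjusted p = 0.00017, 0.002, 0.0045, 0.0065 and 0.01), and none with an estimated correlation (adjusted p = 0.37, 0.61, 0.38, 0.48 and 0.64). Adjusted over the list alone, 6 of 11 flavonoid, 5 of 15 jasmonate, 2 of 9 salicylate and 1 of 11 clock genes fell, against 0 of 12 glucosinolate genes. Over all genes only PAD4 fell (-0.77 ± 0.17, adjusted p = 0.027). The first 4 lists were called in the opposite direction for the root genotype under a WT shoot (adjusted p = 0.002, 0.0033, 0.019 and 2.9e-05), again none with an estimated correlation (adjusted p = 0.41, 0.46, 0.41 and 0.30).

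In total 389 genes were called, 171 higher and 218 lower, of which 38 and 40 passed 1 on the log2 scale. RCI2B fell from 1800 ± 135 to 94 ± 17.4 CPM and CPD fell 14.4-fold. Other large falls, within the same limit on level and overlap, were those of AT5G52020 (-1.84), AT2G41640 (-1.79), AT2G25460 (-1.77) and FRB1 (AT5G01100, -1.33), and other large rises those of AT5G26260 (2.22-fold), AT5G66080 (1.89-fold), AT1G03230 (1.79-fold) and UGT85A1 (AT1G22400, 1.78-fold). AT2G25460 and UGT85A1 each lost their call in 11 of 21 alternatives (adjusted p up to 0.18 and 0.25) and AT5G26260 in 7 (up to 0.14). The count depended on single libraries: it was 690 without cpd/WT replicate 2, 86 without cpd/WT replicate 3, 190 without cpd/WT replicate 4, and 100, 99, 590 and 92 without cpd/cpd replicates 1, 3, 4 and 5. It was 1229 with DESeq2 and 3721 without the 4 least typical libraries. The balance of directions turned as well: 44% of called genes were higher, but 56.7% without cpd/WT replicate 2, 56.1% without cpd/cpd replicate 4, 61.8% without the 4 least typical libraries, 57.5% with limma sample weights and 62.9% of the 35 called against a 1.2-fold change.

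The next question was what a brassinosteroid-deficient shoot does to a WT root. Genes of auxin response fell in the root. GH3.3 (AT2G23170), which encodes an auxin-conjugating enzyme, fell from 9.97 ± 2.77 to 3.64 ± 1.21 CPM (adjusted p = 0.0057) and GH3.1 (AT2G14960) by 0.93 on the log2 scale. Of 12 auxin response genes 3 fell, 4 adjusted over the list alone (camera adjusted p = 0.00076, and adjusted p = 0.24 with an estimated correlation). Among 18 aquaporins 6 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0012, and adjusted p = 0.24 with an estimated correlation): the vacuolar water channel genes TIP1-1 (AT2G36830, -0.49 ± 0.09) and TIP2-2 (AT4G17340, -0.92 ± 0.19) fell, and PIP2-5 (AT3G54820, 0.93 ± 0.20) rose. Iron deficiency genes fell for 7 of 18 members, 11 adjusted over the list alone, with BHLH39 (AT3G56980, -1.19 ± 0.33) and BHLH101 (-1.38 ± 0.24) among them (camera adjusted p = 4.6e-07, and adjusted p = 0.24 with an estimated correlation). Every comparison in which this list was called lower had WT/WT as its reference. Camera did not call this list between cpd/cpd and cpd/WT (adjusted p = 0.29) or between cpd/cpd and WT/cpd (adjusted p = 0.3). Its interaction was called positive (camera adjusted p = 0.0062, and adjusted p = 0.53 with an estimated correlation). BHLH101 had 11.5 ± 3.76 CPM in WT/WT, against 4.83 ± 1.11 in WT/cpd, 4.39 ± 0.253 in cpd/WT and 3.69 ± 1.51 in cpd/cpd.

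Flavonoid, glucosinolate, starch and photosynthesis genes rose in WT roots under a cpd shoot. Flavonoid synthesis had 8 of 11 members higher, 9 adjusted over the list alone, with F3H (AT3G51240) up 1.6-fold and UGT78D1 (AT1G30530) up 2.33-fold. Glucosinolate synthesis had 6 of 12 higher, 8 adjusted over the list alone, with CYP79B2 (AT4G39950) up 2.03-fold and CYP83B1 (AT4G31500) up 1.4-fold. Starch metabolism had 8 of 26 higher, 14 adjusted over the list alone, with the phosphorylase gene PHS2 (AT3G46970, 0.59 ± 0.10) and the amylase gene AMY3 (AT1G69830, 0.45 ± 0.09). Photosynthesis had 14 of 27 higher, 25 adjusted over the list alone, with the carbonic anhydrase gene CA1 (AT3G01500) rising from 1.16 ± 0.702 to 7.17 ± 2.19 CPM and LHCB1.1 (AT1G29920) from 0.978 ± 0.662 to 4.87 ± 0.983 CPM. LHCB1 genes are near-identical copies, so the share of each is uncertain. Camera called these lists (adjusted p = 3.5e-08, 7.7e-06, 4e-07 and 6.3e-15), and none with an estimated correlation (adjusted p = 0.20, 0.20, 0.24 and 0.24). The photosynthesis list is also the marker of shoot tissue, and it took 0.32% of counts in cpd/WT against 0.197% in WT/WT, while plastid-encoded genes took 0.0625% against 0.0754%. In the brassinosteroid synthesis list 2 of 10 members rose, also adjusted over the list alone, ROT3 (1.34-fold) and CYP90D1 (1.56-fold), while DWF4 (-0.38 ± 0.15), BR6OX2 (-0.11 ± 0.14), BR6OX1 (-0.42 ± 0.21), DET2 (-0.01 ± 0.10), BAS1 (-0.39 ± 0.15) and BRI1 (-0.14 ± 0.10) were not called, and camera made no call (adjusted p = 0.93).

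Overall counts were 1900 genes, 1296 higher and 604 lower under a cpd shoot, of which 425 and 43 passed 1 on the log2 scale. Within the same limit on level and overlap, the largest rises were those of the regulators MYB15 (AT3G23250, 9.45-fold) and WRKY40 (AT1G80840, 5.24-fold), AT4G29780 (8.75-fold), DIC2 (AT4G24570, 6.28-fold), ELIP1 (AT3G22840, 5.58-fold) and AT5G17350 (5.17-fold; log2 2.37, and 2.97 without WT/WT replicate 2). MYB15 had 48.5 ± 25.8 CPM in cpd/WT against 5.25 ± 3.44 in WT/WT. Within that limit the largest falls were those of the heat-inducible chaperone genes HSP90.1 (AT5G52640, -1.93) and Hop3 (AT4G12400, -1.55), AT1G55240 (-1.69), AT2G38600 (-1.43), UBC17 (AT4G36410, -1.20) and BHLH39. Calls were lost in 10 of 21 alternatives for WRKY40 and UBC17 (adjusted p up to 0.093 and 0.11), in 9 for DIC2 and AT5G17350 (up to 0.11 and 0.083) and in 8 for BHLH39 (up to 0.10). The count was 893 without WT/WT replicate 1, 1106 without WT/WT replicate 3 and 1206 without cpd/WT replicate 4. With limma sample weights it was 3768, of which 58.6% were higher, against 68.2% here.

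On a cpd root, auxin response genes were again lower under a cpd shoot than under a WT shoot, and so were lateral root, defence and phosphate starvation genes. Camera called neither the defence nor the phosphate list between cpd/cpd and WT/WT (adjusted p = 0.38 and 0.81). The phosphate transporter gene PHT1-4, for instance, had 55.8 ± 27.7 CPM in WT/cpd, against 21.8 ± 3.95 in cpd/cpd and 19.2 ± 3.28 in WT/WT. GH3.3 fell from 8.31 ± 2.27 to 3.04 ± 1.35 CPM (adjusted p = 0.0065), GH3.1 by 0.97 and GH3.5 (AT4G27260) by 0.60 on the log2 scale. Auxin response had 4 of 12 members lower, 8 adjusted over the list alone. Lateral root formation had 2 of 17 lower, 3 adjusted over the list alone, the initiation regulators PUCHI (AT5G18560, -1.02 ± 0.19) and LBD16 (AT2G42430, -0.73 ± 0.20), of which LBD16 lost its call in 10 of 21 alternatives (adjusted p up to 0.16). Salicylate and camalexin defence had 6 of 9 lower, also adjusted over the list alone, such as FMO1 (AT1G19250), PAD4 (-0.95 ± 0.17) and the camalexin synthesis gene PAD3 (AT3G26830, -0.99 ± 0.18). FMO1 stood at 9.75 ± 8.41 CPM in WT/cpd and at 0.159 ± 0.058 in cpd/cpd. Its range in WT/cpd, 0.129 to 22.5 CPM, overlapped that in cpd/cpd, 0.0867 to 0.22 CPM. Phosphate starvation had 4 of 14 lower, 12 adjusted over the list alone, with PHT1-4 (-1.35 ± 0.23) and PAP17 (-1.58 ± 0.28). Camera called these lists (adjusted p = 2.6e-07, 0.025, 1.2e-08 and 1.6e-09), and none with an estimated correlation (adjusted p = 0.10, 0.11, 0.10 and 0.20). TIP2-2 fell by 1 on the log2 scale, and 3 of 18 aquaporins fell, with 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.13).

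Secondary wall and xylem genes had 2 of 24 members higher, also adjusted over the list alone, FLA12 (AT5G60490, 0.64 ± 0.13) and the wall regulator MYB46 (AT5G12870, 0.68 ± 0.18), with camera adjusted p = 0.0019 and adjusted p = 0.86 with an estimated correlation. MYB46 lost its call in 9 of 21 alternatives (adjusted p up to 0.16). Among 10 brassinosteroid synthesis genes CPD fell adjusted over the list alone and missed the call over all genes (adjusted p = 0.069), and camera made no call for the list (adjusted p = 0.70). The log2 fold changes were 0.11 ± 0.15 for DWF4, 0.12 ± 0.14 for BR6OX2, 0.12 ± 0.20 for BR6OX1, 0.05 ± 0.08 for ROT3 and -0.03 ± 0.10 for DET2, and BAS1 (-0.28 ± 0.15) and BRI1 (-0.13 ± 0.10) were not called either.

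A total of 973 genes were called, 296 higher and 677 lower under a cpd shoot, of which 28 and 294 passed 1 on the log2 scale. Within the same limit on level and overlap, the largest rises were those of AT4G34950 (3.92-fold, from 9.48 ± 2.5 CPM to a widely spread 37.4 ± 24.7 CPM), the glutathione transferase gene GSTF14 (AT1G49860, 2.64-fold), the ethylene response factor gene ORA59 (AT1G06160, 2.38-fold), EARLI1 (AT4G12480, 2.27-fold), AT4G24350 (2.25-fold) and TSA1 (AT1G52410, 2.08-fold). The largest falls within it were those of CYP71A12 (-3.64), AT2G18690 (-2), GSTF7 (AT1G02920, -1.90), which has a near-identical neighbour and is uncertain, AT2G25460 (-1.88), AT1G71140 (-1.86) and AT2G41640 (-1.79). The count was 455 without WT/cpd replicate 1, 569 without WT/cpd replicate 3, and 485, 449 and 520 without cpd/cpd replicates 1, 3 and 5. It was 1681 with DESeq2, 500 when only these groups were fitted and 2618 without the 4 least typical libraries. Of called genes 30.4% were higher, but 47.9% without those 4 libraries and 56.4% of 4272 with limma sample weights, where the balance turned.

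Grafts that were cpd throughout were then compared with grafts that were WT throughout. Starch metabolism rose for 15 of 26 members and 21 adjusted over the list alone. PHS2 rose from 37.8 ± 3.57 to 66 ± 3.76 CPM (adjusted p = 0.00016), ADG1 1.68-fold and the glucan phosphatase gene SEX4 (AT3G52180) 1.69-fold. Auxin response fell for 5 of 12 members, 7 adjusted over the list alone, with GH3.3 (-1.72 ± 0.28) and GH3.1 (-1.11 ± 0.21). Brassinosteroid inactivation fell for 2 of 5 members, also adjusted over the list alone, among them BAS1 (-0.80 ± 0.15). These 3 lists were called by camera (adjusted p = 1.2e-19, 3.1e-07 and 0.0012) and also with an estimated correlation (adjusted p = 0.049 for each with an estimated correlation).

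Other lists were called with the preset correlation only. Secondary wall and xylem had 9 of 24 members higher, 16 adjusted over the list alone, including the cellulose synthase gene CESA8 (AT4G18780, 0.58 ± 0.14) and IRX8 (AT5G54690, 0.66 ± 0.16). Iron deficiency had 8 of 18 lower, 10 adjusted over the list alone, with BHLH101 (-1.63 ± 0.24) and BHLH38 (AT3G56970, -2.30 ± 0.46). Aquaporins had 5 of 18 lower and 1 higher, 7 and 1 adjusted over the list alone, with TIP1-1 (-0.63 ± 0.09) and TIP2-2 (-1.07 ± 0.19) lower. The camera adjusted p values were 8.7e-11, 2.6e-10 and 3.3e-05, and with an estimated correlation the adjusted p was 0.25, 0.079 and 0.079. Suberin (7 of 16 lower, 7 adjusted over the list alone) and the Casparian strip list (4 of 10 lower, 7 adjusted over the list alone) were called as well (adjusted p = 2.1e-06 and 5.2e-06, and adjusted p = 0.27 and 0.28 with an estimated correlation). In cpd/cpd replicate 4 CASP1 stood at 33.9 CPM against 62.7 to 72.8 in the other libraries of that group. Photosynthesis had 10 of 27 higher, 24 adjusted over the list alone (adjusted p = 5e-14, and adjusted p = 0.28 with an estimated correlation), and took 0.305% of counts in cpd/cpd, with 0.453% in replicate 4.

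The whole grafts differed in 1326 genes, 777 higher and 549 lower, of which 224 and 104 passed 1 on the log2 scale. RCI2B fell 21.6-fold and CPD 16-fold, followed, within the same limit on level and overlap, by AT4G01390 (-1.78), and the largest rises within it were those of AT4G12500 (4.32-fold), TSA1 (3.16-fold) and TED6 (AT1G43790, 3.16-fold). In brassinosteroid synthesis 4 of 10 members rose and 1 fell, also adjusted over the list alone: CYP90D1 rose 2.5-fold, BR6OX2 2.17-fold, DWF4 1.88-fold and ROT3 1.37-fold, while BR6OX1 (0.29 ± 0.20), DET2 (-0.10 ± 0.10) and BRI1 (0.07 ± 0.10) were not called, and camera made no call (adjusted p = 0.56). The count was 686, 799, 867, 2173 and 682 without WT/WT replicates 1, 2, 3, 4 and 5, and 760 and 647 without cpd/cpd replicates 1 and 3. It was 2105 with DESeq2, 4959 without the 4 least typical libraries and 6398 with limma sample weights, of which 55.8% were higher, against 58.6% here.

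Whether the effect of the root genotype depended on the shoot was tested by the interaction. A negative interaction means that the cpd root raised a gene less, or lowered it more, under a cpd shoot than under a WT shoot. Defence, jasmonate, flavonoid and phosphate starvation genes had negative interactions. Jasmonate and wounding genes had 7 of 15 members with a negative interaction, 9 adjusted over the list alone. AOS (AT5G42650), an enzyme of jasmonate synthesis, had 53.5 ± 25.5 CPM in WT/cpd and 41 ± 13.1 in cpd/WT, against 21.1 ± 3.48 in WT/WT and 28.4 ± 4.98 in cpd/cpd. The repressor gene JAZ1 (AT1G19180) had an interaction of -2.51 ± 0.50. Salicylate and camalexin defence had 5 of 9 negative, 7 adjusted over the list alone, with PAD4 at -1.87 ± 0.24. Flavonoid synthesis had 5 of 11 negative, 7 adjusted over the list alone, with F3H at -0.92 ± 0.21 and its regulator MYB12 (AT2G47460) at -1.60 ± 0.38. Phosphate starvation had 4 of 14 negative, 12 adjusted over the list alone, with PHT1-4 at -1.64 ± 0.33 and PPSPASE1 at -3.18 ± 0.67 (-2.44 without WT/cpd replicate 1). Camera called these lists (adjusted p = 1.5e-05, 6.6e-07, 6.6e-07 and 2.4e-07), and none with an estimated correlation (adjusted p = 0.46, 0.31, 0.31 and 0.36).

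The Casparian strip list had a positive interaction for 1 of 10 members, 3 adjusted over the list alone, CASP4 at 1.2 ± 0.23 (camera adjusted p = 0.00078, and adjusted p = 0.52 with an estimated correlation). Among the brassinosteroid genes ROT3 had an interaction of -0.37 ± 0.11 (adjusted p = 0.039, lost in 13 of 30 alternatives with values up to 0.40), while CPD (-0.34 ± 0.20), DWF4 (0.49 ± 0.21), BR6OX2 (0.22 ± 0.20), BR6OX1 (0.54 ± 0.29), DET2 (-0.01 ± 0.14), BAS1 (0.11 ± 0.21) and BRI1 (0.01 ± 0.15) were not called. Of 11 clock genes 1 had a positive and 2 a negative interaction, also adjusted over the list alone, with no camera call (adjusted p = 0.10): LHY (AT1G01060) stood at -1.14 ± 0.21 and LUX (AT3G46640) at 0.56 ± 0.13.

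In total 1613 genes had an interaction, 480 positive and 1133 negative, of which 29 and 662 passed 1 on the log2 scale. Among called genes with a mean log2 CPM of at least 3, the most negative were AT4G29780 (-5.38), AT5G39670 (-4.78), MYB15 (-4.77), DIC2 (-4.66), AT5G17350 (-4.63, and -5.25 without WT/WT replicate 2) and AT4G27654 (-4.61), and the most positive AT4G34950 (2.24), AT5G14920 (1.43), AT4G24015 (1.36), AT3G15356 (1.36), CASP4 and AT1G09460 (1.18). AT3G15356 lost its call in 16 of 30 alternatives (adjusted p up to 0.11) and AT4G24015 in 11 (up to 0.08). The spread of AT4G29780 within groups was large, with 148 ± 139 CPM in WT/cpd and 132 ± 82.2 in cpd/WT, against 15.3 ± 11.3 in WT/WT and 30.8 ± 23.2 in cpd/cpd. In a list of 24 early-response genes, chosen after this pattern was seen, 18 had a negative interaction. The count was 1050 without WT/WT replicate 1, 1060 without WT/cpd replicate 1, 1067 without cpd/cpd replicate 5 and 2968 without the 4 least typical libraries. Positive interactions made up 29.8% of the called genes, but 44.3% without cpd/WT replicate 2, 45.4% without the 4 least typical libraries and 50.6% of 4129 with limma sample weights.

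**Figure D3:**
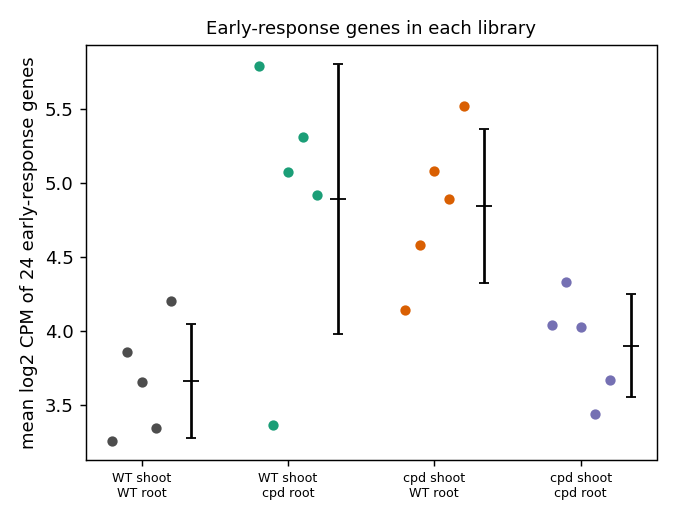
Mean log2 CPM of 24 early-response genes (vertical axis) in each library by group, with the mean and SD of 5 libraries at the right of each group. The reciprocal grafts reach 5.79 in WT/cpd replicate 1 and 5.52 in cpd/WT replicate 5, while WT/cpd replicate 2 lies at 3.37.

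**Figure D4:**
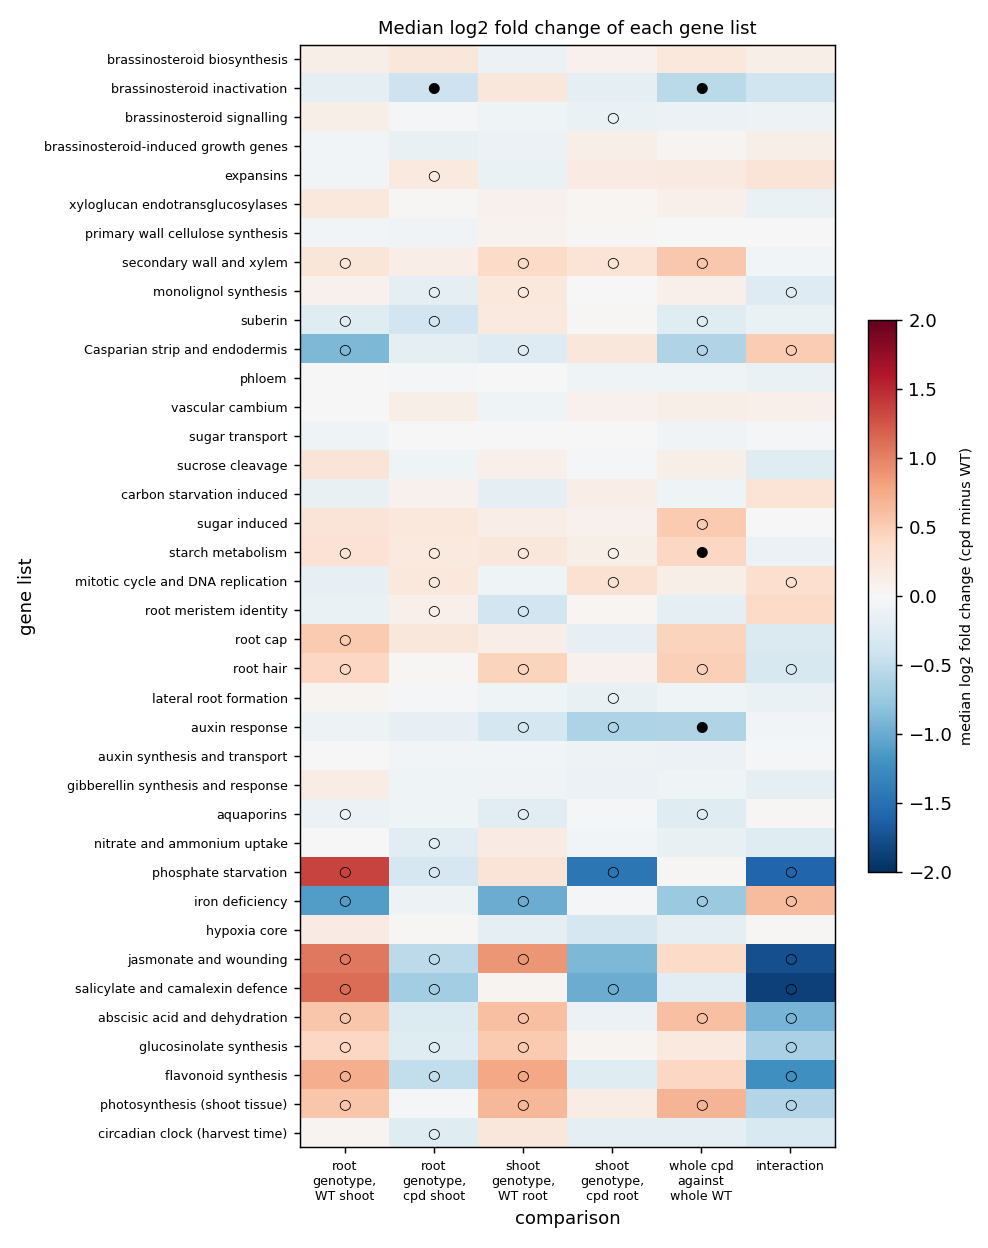
Median log2 fold change of the 38 gene lists (vertical axis) in the 6 comparisons (horizontal axis), cpd minus WT, with blue for lower and red for higher. Open circles mark lists called by camera with the preset correlation and filled circles those also called with an estimated one, which are 3 lists in the whole grafts and 1 for the root genotype under a cpd shoot.

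Across genes, which are not independent replicates, the root effect under a WT shoot and that under a cpd shoot had Pearson's r = -0.1 and Spearman's rho = -0.097, with no shared libraries. This r had a jackknife SE of 0.136 and ran from -0.136 without WT/WT replicate 2 to -0.018 without WT/WT replicate 4. Genes called in both comparisons were nevertheless more often of the same sign than independent lists would give: 53 were higher in both (10.6 for independent lists), 43 lower in both (7.1) and 29 opposite (19.1). For the shoot effect on a WT root and on a cpd root r was -0.169 (jackknife SE 0.155, from -0.209 without WT/cpd replicate 5 to -0.072 without WT/cpd replicate 1) and rho -0.035, with 66 genes higher in both (18.4), 29 lower in both (19.6) and 104 opposite (50.6). The mean root effect and the mean shoot effect had r = 0.086, against -0.003 in simulated unchanged groups. Its jackknife SE was 0.165, and its sign turned with 1 library, from -0.029 without WT/cpd replicate 2 to 0.162 without WT/WT replicate 4. The root effect under a WT shoot and the shoot effect on a WT root share the WT/WT libraries. Their r was 0.666 against 0.505 in simulated unchanged groups that shared these libraries in the same way, and their covariance 0.118 against 0.023. With the WT/WT libraries split, so that the effects shared none, r was on average 0.478 (0.421 to 0.555 over 10 splits). The simulated 0.505 is no reference for this value, and split libraries were not simulated. Of genes called in both, 515 were higher in both, 149 lower in both and 8 opposite, counts for which the shared libraries leave no simple expectation.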

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

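Chosen only after the result was seen were the tests of handling at harvest, of time of day, of exchanged or wrong labels, and of shoot tissue by the photosynthesis genes alone. Of 484 tests of a value within a group 36 found 1 library far from the rest, spread over 15 libraries, where chance gives about 1 in 20, or 24.2.

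The 24 early-response genes, chosen after the pattern was seen, had a median interaction of -2.28: 14 were higher in WT/cpd and 10 in cpd/WT than in WT/WT, and 9 were lower in cpd/cpd than in WT/cpd, but only 1 was lower in cpd/cpd than in cpd/WT (median -0.94). Library depth is argued against, since thinning every library to the lowest total, 13417029 counts, left the median at -2.29. Handling or plant state that varied between libraries of a group stays open: the spread of the score within groups (SD 0.58) lay at percentile 100 of random lists, but genes chosen as varying together must exceed random ones, so this decides nothing. Another time of day at harvest cannot be told apart either. The morning minus evening clock score differed by 0.41 between reciprocal and whole grafts (permutation p = 0.007, two-sided). The clock list was called lower in cpd/cpd than in cpd/WT (camera adjusted p = 0.01, and adjusted p = 0.64 with an estimated correlation). That list holds both morning and evening genes, so its call in 1 direction cannot decide on time of day. The evening genes TOC1, ELF4 and GI went against such a shift, but only within 2 standard errors. Under the rule first set, by which every morning and evening gene had to move its way, they would have counted against it. The limit of 2 standard errors was added after the values were seen. An effect of unlike shoot and root genotypes, which the design names, stays open and untested.

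The library least like its own group, which every group must have, was WT/WT replicate 4, WT/cpd replicate 2, cpd/WT replicate 2 and cpd/cpd replicate 4, and in WT/cpd replicate 2 (mean r 0.9648) lay hardly below replicate 1 (0.9684). Depth is argued against, since after thinning 4 of the 4 still had the lowest mean correlation of their group. In scores of root and shoot genotype from genes changed alike in both backgrounds all 20 libraries lay on their labelled side of 0.5. WT/WT replicate 4, at 0.37 for the shoot, lay within the SD of the shoot scores (0.17) from 0.5, so the rule first set could not decide on exchanged labels. It has no partner, since every cpd shoot library scored at least 0.74, which argues against an exchange. That condition was added after the scores were seen. A wrong label of 1 library is argued against too, since each of the 4 lay at least 0.37 from the nearest library of the other genotype (SD of the shoot scores 0.17). No biological explanation was tested, nor was a pool of roots from different grafts.

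Photosynthesis genes were higher under a cpd shoot on a WT root, by 0.93 (95% interval 0.40 to 1.45) in mean log2 CPM, with 26 of 27 members above 0. Shoot tissue in the root samples may be the source and cannot be told apart from a change in the root. The shoot epidermis score, from 7 of 16 marker genes, the few counted well enough in these roots, differed by -0.03 (-0.50 to 0.44). The bound first set against shoot tissue, an upper limit under 0.5 times the photosynthesis rise, was met only narrowly and inside the interval of that rise, and markers expressed in roots can hide a small share, so it was too weak to decide. On cpd roots the share of photosynthesis counts did not differ detectably with the shoot (exact permutation p = 0.79, two-sided). That share was 0.292 ± 0.079% (SD) in WT/cpd and 0.305 ± 0.085% in cpd/cpd, against 0.197 ± 0.048% in WT/WT and 0.32 ± 0.079% in cpd/WT. It was thus lowest in WT/WT, and the rise was not particular to a cpd shoot.

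Of the other libraries far from their group, WT/WT replicate 2 was low in PLT3 (44.2 CPM) and replicate 3 low in C4H (602 CPM). WT/WT replicate 4 was high in AT1G03230 (123 CPM) and UGT85A1 (19.1 CPM). WT/WT replicate 5 was low in UGT78D1 (10.1 CPM) and in total counts (15892095, or 15.9 M). WT/cpd replicate 1 was high in OCT1 (105 CPM), PPSPASE1 (89.4 CPM) and PIP2-5 (12.9 CPM). WT/cpd replicate 2 was low in CYP86A1 (90.6 CPM) and ABCG2 (41.6 CPM) and high in ORA59 (6.81 CPM). WT/cpd replicate 4 was low in CPD (2.68 CPM) and high in BR6OX2 (62.1 CPM) and BR6OX1 (9.14 CPM). WT/cpd replicate 5 was low in SS3 (14.1 CPM) and AMY3 (43 CPM).

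In cpd/WT, replicate 1 was low in AT5G26260 (286 CPM). Replicate 3 of cpd/WT was low in RCI2B (1560 CPM), SEX4 (8.22 CPM) and the share of plastid-encoded counts (0.0482%). Replicate 4 of cpd/WT was high in AT1G49570 (50.4 CPM), GH3.1 (3.41 CPM) and FMO1 (1.76 CPM). Replicate 5 of cpd/WT was high in HSP90.1 (30 CPM) and Hop3 (33.1 CPM). In cpd/cpd, replicate 3 was high in PHT1-4 (28.7 CPM) and replicate 5 high in LUX (70.7 CPM). Replicate 4 of cpd/cpd held 8 of the 36: it was low in BR6OX2 (34.6 CPM), AT5G46900 (7.11 CPM), CASP4 (4.16 CPM), CASP1 (33.9 CPM), CYP83B1 (241 CPM) and AT4G01390 (5.68 CPM), and high in LBD16 (5.2 CPM) and the share of photosynthesis counts (0.453%).

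For 38 genes named in the comparisons other than the interaction, the root effect differed between the shoots by the test of the interaction (log2, effect under a cpd shoot minus that under a WT shoot). Among these 38, differences above 0 were those of AT4G34950 (2.24), CASP4 (1.2), AT2G39530 (1.13), AT1G55240 (1) and FLA12 (0.67). Below 0 were FMO1 (-5.41), AT4G29780 (-5.38), PBS3 (-5.11), MYB15 (-4.77), DIC2 (-4.66), AT5G17350 (-4.63), WRKY40 (-4.60), CYP71A12 (-4.51), ELIP1 (-2.88), PAD4 (-1.87) and PAD3 (-0.95). Phosphate starvation and root hair genes below 0 were PPSPASE1 (-3.18), PHT1-4 (-1.64), PAP17 (-1.53), XTH26 (-3.51) and PRP1 (-1.91). Secondary metabolism, suberin and photosynthesis genes below 0 were LHCB1.1 (-2.77), MYB41 (-1.61), UGT78D1 (-1.26), CYP79B2 (-0.99), F3H (-0.92) and PAL2 (-0.73). The remaining ones were AT1G49570 (-3.23), AT5G52020 (-3.17), AT2G41640 (-3.10), AT2G25460 (-3.07), OCT1 (-2.93), AT2G18690 (-2.90), BGLU34 (-2.82), BGLU35 (-2.76), GSTF7 (-2.18), FRB1 (-1.56) and ROT3 (-0.37).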

How the results depend on the processing

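The fits without the 4 least typical libraries, with limma sample weights, and of correlations without 1 library were chosen after seeing the data. In the order root genotype under a WT and a cpd shoot, shoot genotype on a WT and a cpd root, whole grafts, interaction, the counts with the replicate block were 1631, 353, 1591, 650, 988 and 1415; the replicate numbers did not pair the libraries (mean r of same-number pairs -0.013). DESeq2 size factors, both filters, the fit without robust estimation and the fit without organelle genes kept every count within 1.5 times. The test against a 1.2-fold change called 638, 35, 284, 233, 232 and 599 genes, since it asks for larger changes. DESeq2 called 1229 for the root genotype under a cpd shoot, 1681 for the shoot genotype on a cpd root and 2105 for the whole grafts. Fits of only the compared groups called 991 for the root genotype under a WT shoot and 500 for the shoot genotype on a cpd root. Without the 4 least typical libraries 3575, 3721, 2618, 4959 and 2968 genes were called, with the shoot genotype on a WT root within 1.5 times. With limma sample weights 5598, 3768, 4272, 6398 and 4129 were called, with the root genotype under a WT shoot within 1.5 times. With each library left out the counts ran from 1037 to 2240, 86 to 690, 893 to 1777, 449 to 1250, 647 to 2173 and 1050 to 2407. Apart from the 1.2-fold test, the cause was not tested, and leaving out libraries both lowered and raised counts.

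Lists called numbered 15, 14, 14, 8, 12 and 12, and 0, 1, 0, 0, 3 and 0 with an estimated correlation. By fry they were 14, 3, 14, 6, 12 and 7, so that the largest drops were for the root genotype under a cpd shoot and the interaction. The cause of these differences was not tested. With a library left out the lists called by camera at the preset correlation ran from 14 to 17, 11 to 16, 14 to 15, 6 to 10, 10 to 14 and 11 to 15.

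Results for named genes and for the lists called with the preset correlation were counted together. Under an alternative 405 of these results lost their call, 14 gained one and 5591 stayed on their side. The lost ones include lists under an estimated correlation or fry, so they do not describe single genes alone. Another 40 reversed, all of genes that were not called and lay near 0. Without the 4 least typical libraries and with limma weights, in that order, these were ROT3 for the root genotype under a cpd shoot (-0.05, -0.04), DET2 for the shoot genotype on a cpd root (0.04, 0.02), and the interactions of DET2 (0.12, 0.05), BAS1 (-0.06, -0.18) and BRI1 (-0.12, -0.08). The BRI1 interaction was also 0.00 with DESeq2 and its size factors and -0.01 with either filter. With a library left out, DET2 ran from -0.11 to 0.01 for the root genotype under a WT shoot, -0.06 to 0.03 and -0.11 to 0.01 for the shoot genotype on a WT and a cpd root, and -0.10 to 0.03 in the interaction. ROT3 ran from -0.03 to 0.06 for the root genotype under a cpd shoot and -0.01 to 0.08 for the shoot genotype on a cpd root, BRI1 from 0.00 to 0.12 in the whole grafts and -0.08 to 0.07 in the interaction, and BAS1 from 0.00 to 0.17 in the interaction. The cause was not tested. Named genes that lost their call in at least 7 alternatives are given with their comparisons, and each other named gene that was called lost it in at most 6. The 14 gained calls were those of CPD for the shoot genotype on a cpd root (5), of BR6OX1 for the root genotype under a cpd shoot (4), the whole grafts (1) and the interaction (1), and of BAS1 for the root genotype under a cpd shoot (2) and the shoot genotype on a cpd root (1). On simulated counts with the real depth, spread and 5 replicates, 56.1% of 1.5-fold changes were recovered for the root genotype under a WT shoot and 25.4% for the interaction. With every library thinned to the lowest total, 1425 genes had a called interaction, against 1613.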

Other observations

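Chosen only after the result was seen were the tests of a stretch of another genome, of clustering along chromosomes and of the brassinosteroid feedback. Other gene lists changed as well. Abscisic acid and dehydration genes rose in cpd roots under a WT shoot, for 5 of 13 members, also adjusted over the list alone, and in WT roots under a cpd shoot, for 4 of 13, 7 adjusted over the list alone (camera adjusted p = 0.00011 and 4.8e-05, and adjusted p = 0.37 and 0.24 with an estimated correlation). Jasmonate and wounding genes rose for 3 and 5 of 15 members, 5 and 10 adjusted over the list alone (adjusted p = 0.0033 and 6.1e-06, and adjusted p = 0.46 and 0.27 with an estimated correlation). Root hair genes rose in WT roots under a cpd shoot for 6 of 19 members, 8 adjusted over the list alone, and in the whole grafts for 7, 9 adjusted over the list alone (adjusted p = 5.5e-06 and 1.1e-06, and adjusted p = 0.41 and 0.35 with an estimated correlation). Secondary wall and xylem genes rose in WT roots under a cpd shoot for 4 of 24 members, 10 adjusted over the list alone (adjusted p = 7.7e-06, and adjusted p = 0.41 with an estimated correlation). Of 38 lists 12 were called in none of the 6 comparisons by camera, among them brassinosteroid synthesis, sugar transport, sucrose cleavage, carbon starvation, primary wall cellulose synthesis, phloem, cambium, gibberellin and hypoxia genes. Beside that, edgeR called 9 of 19 xyloglucan endotransglucosylase genes in cpd roots under a WT shoot, 4 higher and 5 lower, so that this list moved both ways. So did brassinosteroid synthesis in that comparison, with 4 of 10 members higher and 1, CPD itself, lower. Gibberellin genes had 3 of 14 members higher and 2 lower. Camera tests a shift in 1 direction, so for such lists the lack of a call does not mean that no member changed.

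Genes that changed at least 4-fold the same way in cpd roots under both shoots numbered 13, against 1 for the shoot genotype on both roots; these genes were chosen after their values were seen. Besides CPD and RCI2B, MRD1 (AT1G53480) had a mean of 50.1 CPM in WT roots and 0.415 in cpd roots. AT4G04223 had 0.192 CPM in WT roots (42 counts in all) and 18.7 in cpd roots, AT4G18150 had 0.0822 (18 counts) and 8.34, and MPC (AT3G19350) had 0.037 (8 counts) and 2.7.

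RCI2B was low in every cpd root, and its copy RCI2A lies beside it. Reads that moved to RCI2A are argued against: RCI2A changed by -85.1 CPM under a WT shoot, while RCI2B lost 1950 CPM. A stretch of another genome around RCI2B may be a cause and cannot be told apart, since 1 of its 100 tested neighbours was called under both shoots against 0.46 by chance (exact hypergeometric test, p = 0.37). Over all 96 genes changed alike under both shoots, 8 pairs lay within 10 tested genes of each other, where random sets had a median of 4 (permutation p = 0.077 over 10000 random sets), so clustering stays open too.

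A hypothesis is that a WT shoot does not restore the hormone feedback in a cpd root. The mean log2 CPM of DWF4, BR6OX2 and CYP90D1 in cpd roots was -0.16 (95% interval -0.34 to 0.01) under a WT shoot relative to a cpd shoot, against a root effect of 1.07 under a cpd shoot (exact permutation p = 0.11, two-sided, 252 splits). These values are consistent with it, but only narrowly, since the lower end of the interval lies close to the bound set for the test, and the 3 genes were chosen after their values were seen.

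Random splits of the same libraries were drawn, 100 for each comparison with the real one included, so that the smallest possible share was 0.01. In each comparison under 0.05 of the splits called as many genes as the real one, without adjustment over the comparisons. Chance is not excluded by this, since in some comparisons an exchange of 2 libraries called nearly as many genes or more. For the root genotype under a WT shoot the real split called 1972 genes, and it alone (1 split) reached that; the highest other, with WT/WT replicate 4 and WT/cpd replicate 2 exchanged, called 1776. For the shoot genotype on a WT root, the whole grafts and the interaction the real counts were 1900, 1326 and 1613, and the highest others 68, 133 and 249 (1 split each). The splits for the interaction mixed the labels of all 20 libraries, which also removed the effects of root and shoot genotype. They ask about any difference between the groups, so they cannot decide about the interaction alone. Under a cpd shoot 2 splits reached the real 389: exchanging cpd/WT replicate 2 and cpd/cpd replicate 4 called 2459, several times the real count. On a cpd root 2 splits reached the real 973, and exchanging WT/cpd replicate 4 and cpd/cpd replicate 4 called 1971. What in the samples gave such counts was not tested.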
